A study of Mus musculus with 12 samples.

How the data were processed

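The series measured RNA from PUER cells on 12 Affymetrix arrays. PUER cells are a mouse myeloid progenitor line that lacks its own PU.1, grows in interleukin-3 (IL-3) and carries PU.1 fused to the hormone-binding part of the estrogen receptor; 4-hydroxytamoxifen (OHT) switches the fusion protein on. Per the labels, cells grew with 5 ng/ml IL-3, OHT was given at 100 nM, and RNA was taken at 0 h (no OHT) and after 24 h. Of the 12 arrays, 6 are of the Mouse Genome 430 2.0 design and 6 of the Mouse Exon 1.0 ST design, with 3 arrays per condition label in each. Per the labels' protocols, biotinylated sense-strand DNA was made with the whole-transcript labelling assay from 300 ng of total RNA for the 430 arrays, and from 1.5 µg with a step that reduces ribosomal RNA for the exon arrays. The usual target for the 430 design is antisense RNA, so whether this label describes the 430 arrays is in doubt. This was not tested here.

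The values are the log2 signals that the authors deposited, 1 table per array design. Per the submitters' processing notes they were made with Affymetrix Expression Console; the summarization method is not given in the sources used here. For the exon arrays those notes also name genome build mm8, so no coordinates are printed. The values run from 2.43 to 15.02 on the 430 arrays, where array medians lie between 5.78 and 5.87, and from 0.649 to 13.89 on the exon arrays, where they lie between 5.39 and 5.42. Each design was tested within its own table, because the tables were made separately. Arrays have no read depth; the number of arrays limits the precision, and no detection calls were used, so a fold change measured from a dim group may understate the change.

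On the 430 arrays 64 control probe sets were set aside, which left 45037 probe sets; all 23238 transcript clusters of the exon table were tested. Gene names came from the platform annotation given for each design, with symbols updated through Entrez identifiers to the RefSeq annotation of assembly GRCm38.p6. Of the 430 probe sets, 34945 had 1 gene symbol (34741 matched that annotation), 932 had several and 9160 had none. Of the exon transcript clusters, 14939 had 1 symbol (14884 matched), 989 had several and 7310 had none. Features with several symbols or none were tested and counted but not named. A gene was represented on each design by its feature with 1 symbol and the highest mean over the 6 arrays, which gave 18193 genes on the 430 arrays, 14807 on the exon arrays and 13356 on both. On the 430 arrays 9010 genes had several probe sets, and 421 of them had probe sets called in both directions; on the exon arrays the numbers were 131 and 0.

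Conditions were compared as the arrays labelled 24 h minus those labelled 0 h with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment over all features of a design, called at an adjusted p under 0.05). Standard errors are limma's moderated ones; means are given with the SD over the 3 arrays of a group. Nothing in the labels says that the 3 arrays came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical. With 3 arrays against 3, a permutation test of a single gene cannot go below p = 0.1. The difference between designs was tested in 1 limma model over the joined genes, as the 430 change minus the exon change. Gene lists were tested with camera (inter-gene correlation 0.01, adjusted over the 23 lists of a design), again with the correlation estimated from the data, and with fry. The lists hold 448 distinct genes in 491 places, so some lists share members; 22 of the 30 reported PU.1 targets also stand in another list.

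The designs, the gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule names, among genes called in the same direction on both designs with no overlap between the groups' values on either, the 12 with the highest and the 12 with the lowest mean change; a fixed set (Spi1, Esr1, Gata1, Gata2, Cebpa, Csf1r, Itgam, Adgre1, Mpo, Kit, Egr2, Irf8 and Wfdc17); up to 4 members of each list with the largest change on the 430 arrays; and the 3 largest differences between designs in each direction. One rule was added after the values were seen: the 12 highest and 12 lowest changes, averaged with the exon sign turned, among genes called in opposite directions.

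The alternatives were quantile normalization, removal of array medians, a filter on features below the median level, an intensity trend with robust variances, the replicate number as a block, each array left out in turn, an added requirement of a log2 change of at least 1, the mean of all features of a gene, other list tests and a rescaling of the exon values. Offsets before taking logs did not apply, since the tables hold log2 values. Exchanged exon labels, a restriction to features with 1 symbol and the count of genes called in opposite directions were added after the data were seen.

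The scripts were tested on simulated data with real gene means and spreads and 200 changed features. On the 430 arrays (45037 features) 53.7%, 85.1% and 100% of features changed by 0.5, 1 and 2 log2 units were recovered, with 4.79% false calls. On the exon arrays (23238 features) the shares were 5.97%, 49.3% and 81.8%, with 9% false calls. The test of the difference between designs (13356 genes) recovered 99% of differences of 2 log2 units, with 10.8% false calls. The simulated settings differ from the data. Noise was drawn independently for each feature and few features changed, whereas the real fits called 45.8% of 430 features and 24.9% of exon features. Few changes make the adjusted threshold stricter, so these shares do not describe recovery in the data.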

Results

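The study profiled RNA of PUER cells, a mouse myeloid progenitor line in which OHT activates a fusion of PU.1 and the estrogen receptor, to find genes that respond to PU.1. PU.1 is a transcription factor of the myeloid and B-cell lineages. Arrays labelled 0 h (no OHT) and 24 h (100 nM OHT) were run on the Mouse Genome 430 2.0 design, which reads mostly the 3' part of transcripts, and on the Mouse Exon 1.0 ST design, which reads whole transcripts. Each of the 4 groups had 3 arrays. Arrays of 1 group correlated at r = 0.998 or 0.997 on the 430 design and between 0.985 and 0.989 on the exon design, across features. Between groups the correlations were 0.967 to 0.969 and 0.958 to 0.965. The median residual SD per feature was 0.101 log2 units on the 430 arrays and 0.162 on the exon arrays.

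Most genes called on both designs changed in opposite directions between the arrays labelled 0 h and 24 h, and 57 of 3770 changed in the same direction. Across the 13356 genes on both designs the log2 changes correlated at r = -0.861 (Pearson) and -0.723 (Spearman); genes are not independent replicates. Directions are therefore given as the arrays are labelled, and which design has the direction of the culture stays unsettled from the values alone. With the exon labels exchanged, each exon change keeps its size and takes the opposite sign, each exon count of higher genes becomes one of lower genes, and the correlation becomes 0.861. The gene of PU.1 itself does not check the labels, because OHT activates the fusion as a protein. Spi1, which encodes PU.1, had a log2 level of 8.05 ± 0.166 at 0 h and 7.36 ± 0.117 at 24 h on the 430 arrays (SD, n = 3; adjusted p = 0.000468), and 11.85 ± 0.031 and 12.12 ± 0.148 on the exon arrays (adjusted p = 0.116). Esr1, whose hormone-binding part the fusion carries, changed by -2.07 ± 0.188 (SE) on the 430 arrays. Its other 430 probe sets changed less, by -0.46 (adjusted p = 0.00155) and -0.27 (0.0187). On the exon arrays Esr1 showed 0.25 ± 0.0808 and was not called (adjusted p = 0.0713). There it was called without dim features (0.0334), with the variance trend (0.0429) and with gene means (0.0372).

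The first comparison asks which genes differ between the conditions on the 430 arrays. Macrophage identity genes were mostly higher in the arrays labelled 24 h: 17 of 27 were called higher and 4 lower. Single genes changed far more than most. Ptprc, the leukocyte phosphatase CD45, went from 3.70 ± 0.204 to 13.08 ± 0.0841 log2 units (SD, n = 3), a 667-fold difference. Egr2, a transcription factor of macrophage differentiation, was 164-fold higher, and the macrophage marker gene Adgre1 78.5-fold higher. In the other direction Gfi1, a transcriptional repressor of progenitors and granulocytes, was 33.6-fold lower, and Kit, the stem cell factor receptor, 5.16-fold lower.

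Of the 45037 probe sets, 10024 were called higher and 10601 lower in the 430 arrays labelled 24 h, and with a log2 change of at least 1 the counts were 1517 and 2021. Removing each array's median moved the called split to 7265 higher and 11962 lower, so the share of higher calls went from 48.6% to 37.8%. At the gene level 4736 genes were called higher and 4747 lower. Changes of at least 16-fold were skewed, with 77 genes higher and 7 lower. These calls count differences between 6 arrays with a small spread, and many of the called changes are small.

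**Figure D1:**
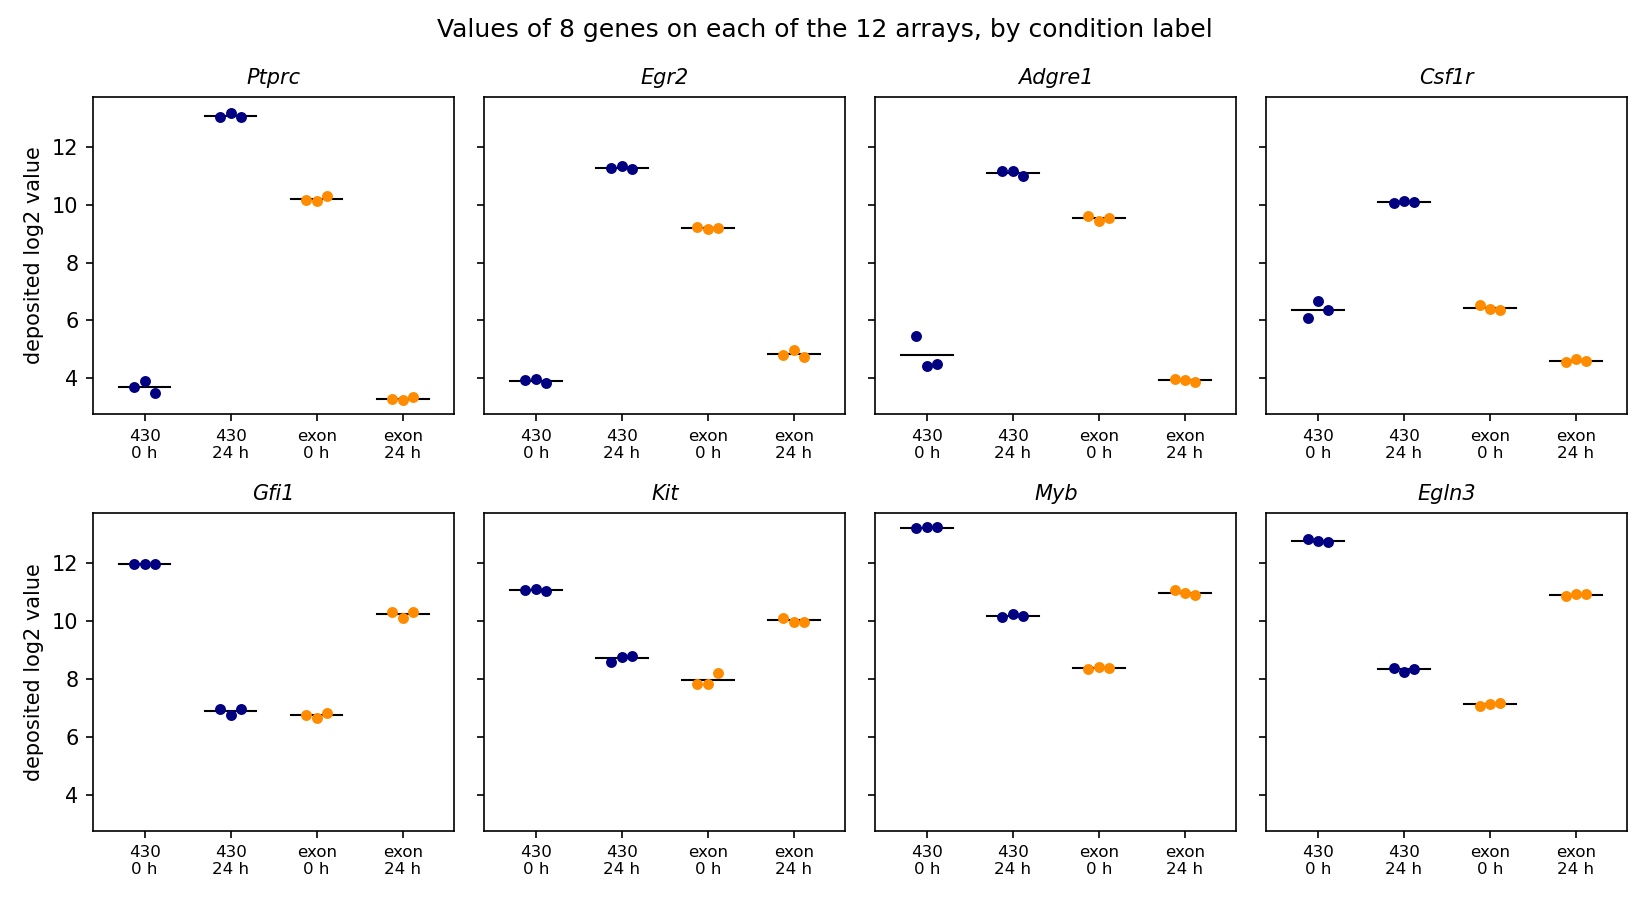
Deposited log2 values (vertical axis) of 8 genes on each of the 12 arrays, grouped by array design and condition label; dots are single arrays and bars are means of 3. Ptprc, Egr2, Adgre1 and Csf1r are higher in the 430 arrays labelled 24 h and in the exon arrays labelled 0 h, and Gfi1, Kit, Myb and Egln3 the other way round.

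Genes reported as PU.1 targets were mostly higher on the 430 arrays labelled 24 h: 24 of 28 measured members were called higher and 2 lower (25 and 2 adjusted over the list alone). Their median log2 change was 1.51 (camera adjusted p = 2.16e-10; adjusted p = 0.0983 with an estimated correlation). Csf1r, the receptor of macrophage colony-stimulating factor, changed by 3.73 ± 0.135 (SE, adjusted p = 9.09e-08), and Itgam, the CD11b integrin chain, by 2.70 ± 0.0642 (adjusted p = 9.64e-09). The other 430 probe sets of Csf1r changed less, by 1.40 (adjusted p = 0.00248) and 0.98 (1.66e-05). Ptpro, a receptor phosphatase, changed by 5.86 ± 0.0706 and Mpeg1, which encodes the pore-forming perforin-2, by 4.45 ± 0.136. The 2 lower members were Ncf4 and Ncf1, subunits of the phagocyte oxidase, at -1.13 ± 0.072 and -0.42 ± 0.0634. Wfdc17, a secreted protease-inhibitor-like protein of macrophages, was 11.1-fold higher (adjusted p = 1.58e-08).

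The macrophage identity list had 17 of 27 members higher and 4 lower (the same numbers adjusted over the list alone), with a median of 1.25 (adjusted p = 3.49e-05; adjusted p = 0.0983 with an estimated correlation). Ccr2, a monocyte chemokine receptor, changed by 7.60 ± 0.12, Tyrobp, the adaptor DAP12, by 7.28 ± 0.0713, and Mertk, a receptor for apoptotic cells, by 5.41 ± 0.0872. Its 4 lower members, named because they are few, were Pparg (-2.26), C5ar1 (-1.22), Gpnmb (-0.74) and Apoe (-0.46). Lysosomal genes were higher in 19 of 28 cases and lower in 1, also adjusted over the list alone (median 0.55, adjusted p = 9.94e-07; adjusted p = 0.0983 with an estimated correlation). The cysteine proteases Ctsc and Ctss changed by 6.23 ± 0.119 and 4.41 ± 0.239, the acid lipase Lipa by 2.01 ± 0.0584 and Cd68 by 1.97 ± 0.0791. The complement and Fc receptor list had 10 of 15 higher and 2 lower over all genes and adjusted over the list alone (median 0.44, adjusted p = 0.000558; adjusted p = 0.145 with an estimated correlation). In it Fcer1g, the common Fc receptor chain, changed by 5.18 ± 0.135, Cfp, the complement factor properdin, by 5.08 ± 0.0667 and Itgax by 4.07 ± 0.108.

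Pattern recognition genes were higher in 16 of 22 cases and lower in 2, again the same adjusted over the list alone (median 0.93, adjusted p = 2.21e-05; adjusted p = 0.104 with an estimated correlation). Clec4n, the fungal receptor dectin-2, went from 4.99 ± 0.179 to 13.52 ± 0.0109 log2 units, a 369-fold difference. Pilra changed by 5.37 ± 0.122, the beta-glucan receptor Clec7a by 3.64 ± 0.0716 and Tlr8 by 3.18 ± 0.167. Interferon response genes were higher in 15 of 19 cases and lower in 2, also adjusted over the list alone (median 0.57, adjusted p = 0.000661; adjusted p = 0.0976 with an estimated correlation). Usp18, a protease that removes ISG15, changed by 5.08 ± 0.134 and Gbp2 by 2.26 ± 0.136. Gbp3, a guanylate-binding protein of the same family, was lower by contrast (-2.50 ± 0.0718), as was Ifit2 (-0.91). Among monocyte and macrophage transcription factors 11 of 24 were higher and 3 lower, the same adjusted over the list alone (median 0.19, adjusted p = 0.00917; adjusted p = 0.0983 with an estimated correlation). The AP-1 subunits Fos and Jun changed by 4.17 ± 0.0829 and 3.47 ± 0.0777 and the inhibitor of differentiation Id2 by 3.92 ± 0.0977. Cebpa, a driver of granulocytic differentiation, was lower (-1.33 ± 0.0954), while Irf8 showed 0.18 ± 0.118 and was not called (adjusted p = 0.25).

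Growth genes were lower as groups. All 23 measured DNA replication genes were called lower on the 430 arrays labelled 24 h, also adjusted over the list alone (median -1.30, adjusted p = 1.18e-12; adjusted p = 0.0976 with an estimated correlation). The uracil glycosylase Ung changed by -2.32 ± 0.0674, the helicase subunit Mcm3 by -1.74 ± 0.0743 and thymidine kinase Tk1 by -1.74 ± 0.0699. MYC and ribosome biogenesis genes were lower in 21 of 22 cases over all genes and adjusted over the list alone, with a median of -1.41 (adjusted p = 2.51e-12; adjusted p = 0.0294 with an estimated correlation). Examples were the spermidine synthase Srm (-2.43 ± 0.0794) and the ribosome assembly genes Rrp12 (-2.27 ± 0.0645), Nop56 (-1.96 ± 0.0593) and Nolc1 (-1.91 ± 0.0646). Mitotic genes were lower in 15 of 19 cases by both counts, over all genes and adjusted over the list alone (median -0.63, adjusted p = 1.72e-06; adjusted p = 0.125 with an estimated correlation), among them the kinases Plk1 (-1.09 ± 0.0762) and Aurka (-1.01 ± 0.067). Cdca8 and Top2a changed by -0.87 each.

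Of 17 glycolysis and hypoxia genes 13 were lower and 1 higher (13 and 2 adjusted over the list alone), with a median of -0.92 (adjusted p = 1.64e-06; adjusted p = 0.0976 with an estimated correlation). The oxygen sensor Egln3 changed by -4.45 ± 0.0659, phosphofructokinase Pfkl by -1.97 ± 0.0835, lactate dehydrogenase Ldha by -1.52 ± 0.0786 and Bnip3 by -1.42 ± 0.0589. Cholesterol synthesis genes were lower in 11 of 18 cases and higher in 2 (11 and 3 adjusted over the list alone; median -0.43, adjusted p = 0.00939; adjusted p = 0.276 with an estimated correlation), and without probe sets below the median level that list was not called (adjusted p = 0.125). Mvd changed by -1.25 ± 0.0754, Dhcr7 by -1.18 ± 0.0734 and Hsd17b7 by -0.91 ± 0.0921, while Fdft1 was higher (0.78 ± 0.0715). The other 430 probe sets of Fdft1 changed less, by 0.255 (adjusted p = 0.0283), 0.29 (0.0115) and 0.03 (0.754). On the exon arrays Fdft1 changed by -0.24 and was not called (0.184), though it was with quantile normalization (0.0262).

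The other 11 lists were not called on the 430 arrays. Many of their members changed, but so did many genes in all: of 18193 genes, 4736 were called higher and 4747 lower. Stem and progenitor genes had 9 of 20 lower and 2 higher (9 and 3 adjusted over the list alone; adjusted p = 0.0507), with Gfi1 (-5.07 ± 0.075), the transcription factors Myb (-3.05 ± 0.0613) and Hlf (-2.30 ± 0.115), and Kit (-2.37 ± 0.0733) among the lower. That list passed the threshold without 0 h array 1 (adjusted p = 0.0397), 0 h array 2 (0.0408), 24 h array 2 (0.0414) or 24 h array 3 (0.045), and also with quantile normalization (0.0463) and with the variance trend (0.0327). Granulocyte genes split, with 10 of 21 lower and 6 higher, the same adjusted over the list alone (adjusted p = 0.155): the antimicrobial peptide gene Camp changed by -3.29 ± 0.0639, while Chil3 changed by 4.76 ± 0.0749, the gelatinase Mmp9 by 4.72 ± 0.114 and myeloperoxidase, Mpo, by 0.90 ± 0.0699. Cytokines and chemokines had 10 of 22 higher and 4 lower (12 and 4 adjusted over the list alone; adjusted p = 0.0664), led by Il18 (7.50 ± 0.123), the neutrophil attractant Cxcl2 (4.42 ± 0.123) and Tnf (1.41 ± 0.0667), with Vegfa lower (-1.29 ± 0.0769). Stress genes had 8 of 15 lower and 2 higher, also adjusted over the list alone (adjusted p = 0.064). Asparagine synthetase, Asns, changed by -1.09 ± 0.0601, Herpud1 by -0.74, Trib3 by -0.73 and Sdf2l1 by -0.63.

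Antigen presentation had 6 of 16 higher and 3 lower, the same adjusted over the list alone (adjusted p = 0.403). Cd80 changed by 3.61 ± 0.185, the invariant chain Cd74 by 3.18 ± 0.0716, H2-DMa by 2.17 ± 0.148 and the peptide transporter subunit Tap2 by -1.02 ± 0.0634. The NADPH oxidase list had 2 of 6 higher and 3 lower, the same adjusted over the list alone (median -0.13, mean 0.53, direction lower in the test; adjusted p = 0.913). The catalytic subunit Cybb changed by 4.38 ± 0.0881 and Cyba by 0.58 ± 0.0812. IL-3 and STAT5 response genes had 5 of 16 higher and 4 lower (7 and 4 adjusted over the list alone; adjusted p = 0.278). The cytokine receptor chain Csf2rb2 changed by 2.82 ± 0.0829, Ccnd1 by 1.23 ± 0.0986, Mcl1 by 0.91 ± 0.0604 and Socs3 by -0.75 ± 0.0851. The Ccnd1 change rests on 1 probe set. Its other 430 probe sets gave 0.10 (adjusted p = 0.267) and 0.12 (0.187), and the exon arrays -0.10 (0.614), none of them called. Markers of other lineages gave no called list. Mast cell and basophil genes had 4 of 19 higher and 5 lower (5 and 5 adjusted over the list alone; median 0.06, mean -0.08, direction lower in the test; adjusted p = 0.941). Mcpt8 changed by -1.48 ± 0.0724 and Ms4a2 by -0.42. Erythroid and megakaryocyte genes had 7 of 20 higher and 2 lower (8 and 2 adjusted over the list alone; adjusted p = 0.289). Nfe2 changed by -1.92 ± 0.077, Vwf by -0.54 and Ppbp by 0.47. Gata1 (0.19 ± 0.0755, adjusted p = 0.0658) and Gata2 (-0.01 ± 0.0927, adjusted p = 0.913) were not called, though Gata1 was called without dim features (0.0291) and with gene means (0.0388). Lymphoid genes had 6 of 20 higher and 4 lower, the same adjusted over the list alone (adjusted p = 0.374). The B-cell linker Blnk changed by 5.07 ± 0.13, Notch1 by -0.77 ± 0.0718 and Il7r by -0.56. Reference genes had 3 of 11 higher and 5 lower (5 and 5 adjusted over the list alone; adjusted p = 0.725). B2m changed by 0.70, Gusb by 0.61, Pgk1 by -0.60 and Polr2a by -0.47.

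The second comparison asks the same of the exon arrays, labelled 24 h against those labelled 0 h. Macrophage identity genes were mostly lower: 17 of 24 were called lower and 3 higher. Ptprc, which is not in that list, went from 10.20 ± 0.0852 at 0 h to 3.30 ± 0.0581 log2 units at 24 h (SD, n = 3), 119-fold lower. Clec4n was 323-fold lower, Adgre1 48.7-fold lower and Egr2 20.5-fold lower. Higher were Nt5e, the ecto-enzyme CD73, by 15.9-fold, the thyroid hormone deiodinase Dio2 by 14.8-fold, Egln3 by 13.7-fold and Gfi1 by 11.4-fold.

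Of the 23238 transcript clusters, 3709 were called higher and 2070 lower, and with a log2 change of at least 1 the counts were 1087 and 725. Quantile normalization moved the called split to 3142 higher and 2661 lower, so the share of higher calls went from 64.2% to 54.1%. At the gene level 2856 genes were higher and 1606 lower; 0 genes were at least 16-fold higher and 45 at least 16-fold lower. With the exon labels exchanged these counts change places.

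Macrophage identity genes were lower in 17 of 24 cases and higher in 3 on the exon arrays labelled 24 h, also adjusted over the list alone (median -1.72, camera adjusted p = 1.25e-10; adjusted p = 0.0445 with an estimated correlation). Tyrobp changed by -6.02 ± 0.182 (SE), Ccr2 by -6.11 ± 0.148 and Mertk by -4.10 ± 0.0911. Reported PU.1 targets had 22 of 25 lower and 1 higher by both counts, over all genes and adjusted over the list alone (median -1.21, adjusted p = 2.3e-14; adjusted p = 0.0445 with an estimated correlation). Csf1r changed by -1.83 ± 0.0894, Itgam by -2.78 ± 0.114 and Ptpro by -2.49 ± 0.0988. The higher member was Ncf4 (0.76 ± 0.103). Pattern recognition genes were lower in 13 of 22 cases and higher in 2, the same adjusted over the list alone (median -0.76, adjusted p = 4.05e-06; adjusted p = 0.0445 with an estimated correlation). Pilra changed by -6.35 ± 0.1 and Tlr8 by -4.74 ± 0.233.

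Lysosomal genes were lower in 16 of 28 cases (19 adjusted over the list alone; median -0.53, adjusted p = 1.81e-09; adjusted p = 0.111 with an estimated correlation), among them Ctsc (-5.44 ± 0.144), Ctss (-4.39 ± 0.0976) and Lipa (-1.67 ± 0.105). The complement and Fc receptor list had 6 of 11 lower and 1 higher, also adjusted over the list alone (median -0.46, adjusted p = 0.000638; adjusted p = 0.111 with an estimated correlation). Fcer1g changed by -5.98 ± 0.146. Monocyte and macrophage transcription factors had 8 of 21 lower and 2 higher, the same adjusted over the list alone (median -0.20, adjusted p = 0.0011; adjusted p = 0.111 with an estimated correlation). Fos changed by -3.61 ± 0.124, Jun by -3.20 ± 0.123 and Id2 by -2.65 ± 0.097, while Cebpa was higher (0.59 ± 0.112, adjusted p = 0.0115). Cytokines and chemokines had 7 of 20 lower and 2 higher (8 and 2 adjusted over the list alone; median -0.19, adjusted p = 0.0119; adjusted p = 0.112 with an estimated correlation). Il18 changed by -5.67 ± 0.0968, Cxcl2 by -3.59 ± 0.332 and Tnf by -2.13 ± 0.257. IL-3 and STAT5 response genes had 4 of 14 lower and 2 higher (7 and 2 adjusted over the list alone; median -0.26, adjusted p = 0.0249; adjusted p = 0.112 with an estimated correlation). Mcl1 changed by -0.74 ± 0.0786.

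The growth lists were higher on the exon arrays labelled 24 h. DNA replication had all 20 measured genes higher, also adjusted over the list alone (median 1.21, adjusted p = 1.68e-11; adjusted p = 0.111 with an estimated correlation). Tk1 changed by 2.60 ± 0.277 and Mcm3 by 1.93 ± 0.154. MYC and ribosome biogenesis had 16 of 17 higher, the same adjusted over the list alone (median 1.20, adjusted p = 3.92e-10; adjusted p = 0.0579 with an estimated correlation). Nop56 changed by 2.05 ± 0.168 and Rrp12 by 1.65 ± 0.0849. Mitosis had 13 of 18 higher (16 adjusted over the list alone; median 0.58, adjusted p = 8.17e-06; adjusted p = 0.112 with an estimated correlation). Aurka changed by 0.95 ± 0.0901 and Cdca8 by 0.90 ± 0.0862. Glycolysis and hypoxia had 11 of 14 higher, also adjusted over the list alone (median 0.66, adjusted p = 4.93e-05; adjusted p = 0.112 with an estimated correlation). Pfkl changed by 1.38 ± 0.103 and Bnip3 by 1.03 ± 0.0916.

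Calls of 3 further exon lists depended on the processing. Cholesterol synthesis had 5 of 17 higher, the same adjusted over the list alone (median 0.30, adjusted p = 0.0335; adjusted p = 0.399 with an estimated correlation). Hsd17b7 changed by 1.49 ± 0.148 and Mvd by 0.97 ± 0.103. The call was lost with quantile normalization (0.077), without dim features (0.224) and without 0 h array 2 (0.0578). Interferon response had 6 of 15 lower and 2 higher (7 and 2 adjusted over the list alone; median -0.27, adjusted p = 0.0397; adjusted p = 0.213 with an estimated correlation). Gbp2 changed by -1.29 ± 0.188 and Gbp3 by 2.24 ± 0.112. The call was lost with quantile normalization (0.077), without dim features (0.16), without 0 h array 1 (0.0639) and without 24 h array 2 (0.0568). Antigen presentation had 5 of 12 lower and 1 higher, the same adjusted over the list alone (median -0.29, adjusted p = 0.0379; adjusted p = 0.132 with an estimated correlation). Cd80 changed by -4.93 ± 0.125 and Cd74 by -3.22 ± 0.201. The call was lost without dim features (0.16) and without 24 h array 1 (0.0639).

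The remaining 8 lists were not called on the exon arrays. Stem and progenitor genes had 6 of 19 higher and 2 lower, the same adjusted over the list alone (adjusted p = 0.133). Myb changed by 2.60 ± 0.0823, Kit by 2.08 ± 0.132 and Hlf by 1.24 ± 0.192. Granulocyte genes had 9 of 21 higher and 6 lower (9 and 7 adjusted over the list alone; adjusted p = 0.651). Camp changed by 1.48 ± 0.193, Chil3 by -4.89 ± 0.161, Mmp9 by -4.93 ± 0.0886 and Mpo by -1.06 ± 0.0802. Stress genes had 8 of 15 higher and 2 lower (8 and 3 adjusted over the list alone; adjusted p = 0.146). Asns changed by 1.20 ± 0.141. NADPH oxidase had 1 of 6 higher and 2 lower, also adjusted over the list alone (adjusted p = 0.13). Cybb changed by -3.79 ± 0.135. Mast cell and basophil genes had 5 of 18 higher and 2 lower (6 and 2 adjusted over the list alone; adjusted p = 0.208). Mcpt8 changed by 1.36 ± 0.0945. Lymphoid genes had 1 of 17 higher and 1 lower, the same adjusted over the list alone (adjusted p = 0.182). Notch1 changed by 0.60 ± 0.0844 and Blnk by -3.22 ± 0.156. Erythroid and megakaryocyte genes had 1 of 16 higher and 1 lower (1 and 0 adjusted over the list alone; adjusted p = 0.651). Their mean was 0.07 and the test's direction lower. Reference genes had 1 of 10 higher and 3 lower (3 and 4 adjusted over the list alone; median 0.11, direction lower in the test, adjusted p = 0.651). Gusb changed by -0.80 ± 0.0851. Gata1 (0.01), Gata2 (0.13) and Irf8 (0.11) were not called (adjusted p = 0.972, 0.473 and 0.555).

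**Figure D2:**
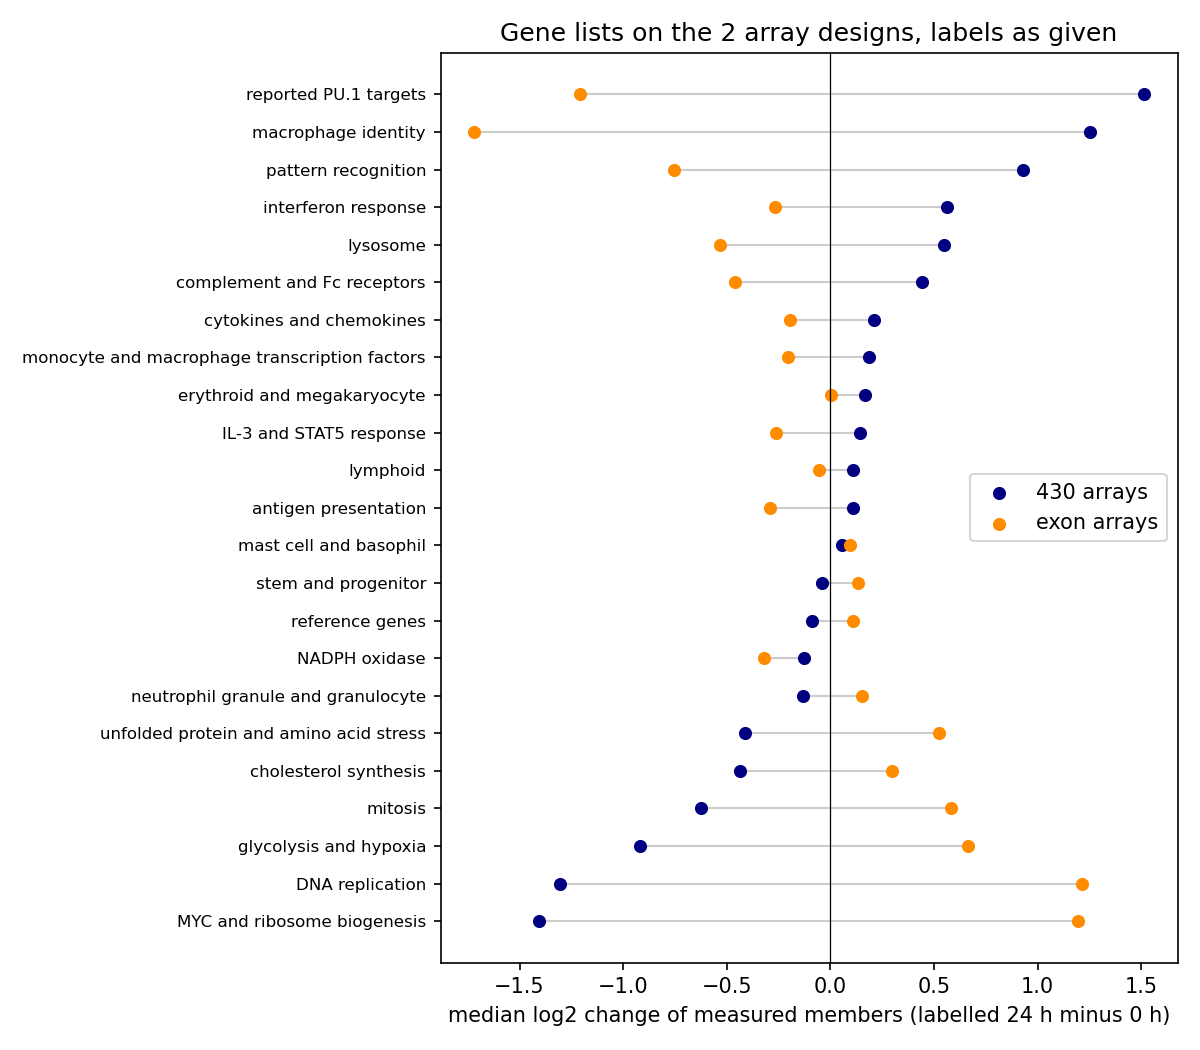
Median log2 change (horizontal axis, arrays labelled 24 h minus 0 h) of the measured members of each of the 23 gene lists, with 1 dot per array design. Reported PU.1 targets lie at 1.51 on the 430 arrays and -1.21 on the exon arrays, DNA replication at -1.30 and 1.21.

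The third comparison asks how far the 2 designs show the same genes. Genes called on both designs moved in opposite directions in 3713 of 3770 cases (98.5%): 1274 were higher on the 430 arrays and lower on the exon arrays, against 410 for independent lists, and 2439 the other way, against 821. Only 57 moved in the same direction (33 higher and 24 lower), against 750 and 449 for independent lists. Of the 877 genes called on both with a log2 change of at least 1 on each, 0 moved in the same direction. Mean log2 levels of genes correlated at r = 0.878 between designs, and each of the 12 arrays lay on the side opposite to its label when set against the other design's change (label-signed r from -0.859 to -0.778 across genes).

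**Figure D3:**
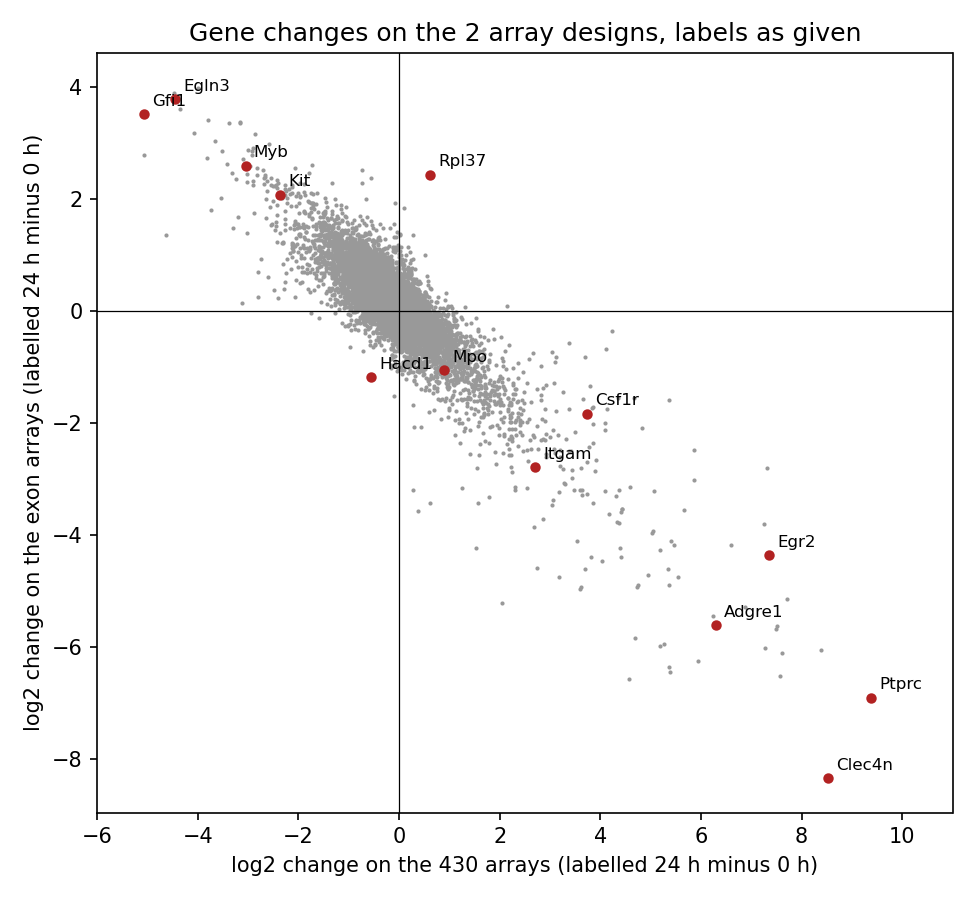
Log2 change of each of 13356 genes on the 430 arrays (horizontal axis) and on the exon arrays (vertical axis), arrays labelled 24 h minus 0 h, with 13 genes marked. The points fall along a line of negative slope (r = -0.861), with Ptprc at 9.38 and -6.90 and Gfi1 at -5.07 and 3.51.

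The genes at the ends of this relation were picked after the values were seen. On the 430 and exon arrays in turn, the protease inhibitor Serpinb12 changed by 8.39 ± 0.0654 and -6.05 ± 0.0867, the macrophage elastase Mmp12 by 7.57 ± 0.157 and -6.51 ± 0.0781, and the succinate receptor Sucnr1 by 7.71 ± 0.151 and -5.15 ± 0.138. Clec4a3 (7.51 and -5.63), Plet1 (6.88 and -5.29) and the surface glycoprotein Cd52 (5.95 and -6.24) followed. At the other end were Rgcc (-5.07 and 2.79), the transglutaminase Tgm2 (-4.35 and 3.61), Aldh3a1 (-4.09 and 3.18), Thbs1 (-3.81 and 2.74), Fmo1 (-3.79 and 3.42), Rhoj (-3.65 and 3.03), the growth factor Nrg4 (-3.37 and 3.35) and Nkg7 (-3.17 and 3.37).

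The 24 genes named for moving the same way on both designs changed less. Higher on both were the ribosomal protein gene Rpl37 (0.62 ± 0.095 and 2.44 ± 0.408), the Mediator subunit Med18 (0.29 and 1.36), Ciao2a (0.51 and 1.00), the splicing factor Srsf5 (0.28 and 0.94), Gm839, Igfbp7, Abhd2, Zfp983, Cit, Kif15, Map3k20 and Rnf185. Lower on both were Hacd1 (-0.56 ± 0.0629 and -1.18 ± 0.224), the splicing factor Sf3b4 (-0.97 and -0.64), Rab11b (-0.72 and -0.71), the telomere protein Acd (-0.57 and -0.60), Rbpms (-0.58 and -0.54), the growth factors Vegfb (-0.48 and -0.60) and Tgfb1 (-0.40 and -0.55), Fbrsl1, Gas2l1, Ppp2r5b, the nuclear receptor Ppard (-0.41 and -0.46) and Pglyrp1 (-0.45 and -0.39). Another 430 probe set of the same gene was called with the other sign for 5 of the 24: Igfbp7, Cit, Map3k20, Rnf185 and Rab11b. With the mean of all probe sets of a gene, Cit, Map3k20 and Rab11b were called with the other sign, and the 430 calls of Igfbp7 (-0.0493, adjusted p = 0.48), Rnf185 (-0.00175, adjusted p = 0.981), Abhd2 (0.03, adjusted p = 0.757), Gas2l1 (-0.09, adjusted p = 0.199) and Tgfb1 (-0.14, adjusted p = 0.145) ended. Removing array medians ended the 430 calls of Igfbp7 (adjusted p = 0.164), Gm839 (0.138), Cit (0.103), Med18 (0.0786) and Abhd2 (0.078). Quantile normalization ended those of Gm839 on the 430 arrays (0.244) and of Rnf185 (0.192) and Abhd2 (0.053) on the exon arrays. Leaving out 1 array ended a call on at least 1 design for 14 of the 24. On the 430 arrays the adjusted p then reached 0.138 for Gm839, 0.124 for Igfbp7, 0.102 for Cit, 0.0676 for Med18, 0.0675 for Abhd2 and 0.0529 for Zfp983. On the exon arrays it reached 0.123 for Rnf185, 0.114 for Abhd2, 0.109 for Sf3b4, 0.108 for Pglyrp1, 0.101 for Zfp983, 0.0831 for Ciao2a, 0.0827 for Map3k20, 0.0741 for Ppp2r5b, 0.0564 for Kif15 and 0.0516 for Ppard. Over all 57 genes the smaller of the 2 absolute log2 changes had a median of 0.312, against 0.638 among the 3713.

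The change itself differed between designs for 7745 of the 13356 genes, which is dominated by the opposite signs. With the exon labels exchanged 3050 genes still differed. Changes had a smaller spread across genes on the exon arrays (SD 0.677 against 0.779 log2 units on the 430 arrays), so differences of scale may enter this count. No rescaled fit was run with the exchanged labels. With the labels as given, the largest differences (430 minus exon) were those of Clec4n, Ptprc and Serpinb12 on the positive side and of Gfi1, Dio2 and Egln3 on the negative side.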

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

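The tests of exchanged labels, of which design carries them and of gene levels were chosen only after the opposite changes had been seen. The rank test was chosen before its own result was seen, but its prediction already names the opposite changes. The counts over other splits were chosen before their results were seen. The change between the arrays labelled 0 h and 24 h differed between the array designs for 7745 genes. The largest differences, as the 430 change minus the exon change in log2 units, were 16.86 for Clec4n, 16.28 for Ptprc and 14.44 for Serpinb12, and -8.58 for Gfi1, -8.35 for Dio2 and -8.22 for Egln3. Each design has 10 splits of its arrays. Of 100 joint combinations of a 430 split with an exon split, 1, the real one, gave as many differing genes. The 99 others were drawn at random, with the exon sign kept or turned. Some keep the real split of 1 design, and another keeps both real splits with the exon sign turned (3050 genes). All other splits mix the labels within groups, so they could hardly give as many, and this count is no separate support. The highest of the others, which keeps the real 430 split, gave 3357.

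The pattern behind these values is that nearly all genes called on both designs moved in opposite directions. Probe annotation or probe design is argued against by the gene levels, which correlated at r = 0.878 between designs, and the authors' normalization by the ranks within each array, whose changes still correlated at r = -0.798. Exchanged condition labels on 1 design remain a candidate explanation. All 6 exon arrays lay on the side opposite to their label, the nearest to 0 at r = -0.778, but this follows from the opposite changes and the likeness of replicates and is no separate test. The list of reported PU.1 targets had a median log2 change of -1.21 on the exon arrays and 1.51 on the 430 arrays, which is consistent with the exchange being on the exon arrays, if PU.1 raises these genes as the list assumes; the values alone do not settle it. The design puts the same contrast on both arrays and names no biological difference between them, so no biological explanation was tested.

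A control probe set outside the comparisons, that for the middle part of beta-actin on the 430 arrays, was 0.253 log2 units higher in the arrays labelled 24 h. Control probe sets moved both ways by as much or more: among bacterial spike-ins BioDn 3' by 0.33 and ThrX 5' by -0.434, with many others not called, and those of Gapdh fell by 0.333 to 0.402. So the value is not read as a change of beta-actin.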

How the results depend on the processing

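The exchange of exon labels, the restriction to features with 1 symbol and the count of genes called in opposite directions were chosen after the data were seen. The counts of called features stayed within 1.5 times under both normalizations, the filter on dim features, the variance trend, the 1-symbol restriction and each left-out array; the 430 count ranged from 17948 to 19378 and the exon count from 4158 to 5355 over left-out arrays. Requiring a log2 change of at least 1 left 3538 probe sets (1517 higher, 2021 lower), 1812 transcript clusters (1087 and 725), 877 genes in opposite directions and 0 in the same direction. The correlation between designs stayed between -0.888 and -0.846 under quantile normalization, the filter, the gene means and the left-out arrays. Removing array medians shifts all changes of a design alike, and the variance trend leaves the changes as they are, so neither could move the correlation. It was not computed for the 1-symbol restriction or the log2 requirement. The same-direction count of 57 was the least stable: 88 with quantile normalization, 136 without dim features, 98 with the variance trend, 97 with gene means, and 20 to 66 with 1 array left out (36 or fewer in each fit without an exon array, except that without 24 h array 3); the cause was not tested. Exchanging the exon labels turned the correlation to 0.861 and put 3713 genes in the same direction and 57 in opposite ones, all by construction of the sign. It also left 3050 genes whose change differed between designs, a count from a separate fit that the sign alone does not fix. Differences of scale between the designs may enter that count. Rescaling the exon values, with the labels as given, left 7609 such genes. With an estimated correlation 1 list was called on the 430 arrays and 3 on the exon arrays. Fry called 22 on the 430 arrays and 20 on the exon arrays. On the 430 arrays it turned the NADPH oxidase list to higher (adjusted p = 0.00239). Unlike camera, fry does not set a list against the other genes. It called even the reference genes on the 430 arrays (adjusted p = 0.0284), so its counts do not single out particular lists. Of the 430 lists not called, the stress list was called with the variance trend (0.0327) and gene means (0.0368), the cytokine list with gene means (0.0447), and the stem and progenitor list with the variance trend (0.0327), quantile normalization (0.0463) and 4 of the left-out arrays (0.0397 to 0.045). With the mean of all probe sets of a gene, the 430 changes of Cit (-0.34), Igfbp7 (-0.0493), Map3k20 (-0.35), Qars (-0.0826), Rab11b (0.19) and Rnf185 (-0.00175) turned sign. Within a design the replicate numbers showed no clear pairing: same-numbered arrays deviated from their group means with r of -0.0548, 0.0396 and 0.132 on the 430 design and -0.0262, 0.00878 and -0.0516 on the exon design. Across designs r lay between -0.133 and 0.113. Only 430 0 h with exon 24 h was positive for every number (0.099, 0.0806 and 0.113), and what this reflects was not tested. The replicate block gave 20245 probe sets, 4280 transcript clusters and 20 same-direction genes. The spread between exon arrays limits small changes there, and signal over background could not be judged without detection calls.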

Other observations

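The gene families here were chosen after the values were seen and are descriptions of these arrays. With camera, 14 families were tested on each design. Because the families were picked from these same values, their p-values are no separate support for the patterns. Genes of cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, moved together: 15 of 16 were lower and 1 higher on the 430 arrays labelled 24 h (median -0.65, adjusted p = 5.05e-06; adjusted p = 0.109 with an estimated correlation), and 13 of 14 were higher on the exon arrays labelled 24 h (median 0.69, adjusted p = 3.37e-06; adjusted p = 0.128 with an estimated correlation). Vars changed by -1.60 and 0.94 on the 430 and exon arrays, Yars by -1.31 and 1.12, and Wars by -1.14 and 1.06. The exception was Qars, at 0.28 on the 430 arrays and, not called, 0.36 on the exon arrays. Its 430 call ended without 0 h array 3 (adjusted p = 0.0742) or 24 h array 2 (0.0756) and with array medians removed (0.0811), and with the mean of its probe sets the change was -0.0826 (adjusted p = 0.248), so this exception is not firm. Translation initiation factor genes and their regulators had 24 of 38 lower and 1 higher on the 430 arrays (adjusted p = 2.63e-05; adjusted p = 0.0811 with an estimated correlation) and 15 of 29 higher and 2 lower on the exon arrays (adjusted p = 0.000589; adjusted p = 0.0834 with an estimated correlation), with Eif3b at -1.32 and 0.87 and Eif2b4 at -1.17 and 0.93. The cationic amino acid transporter Slc7a1 (-1.41 and 1.15), the cystine transporter Slc7a11 (-1.57 and 1.67) and Slc7a5 (-2.02 and 1.55) changed likewise, while Slc7a2 changed by 1.32 and -0.59. Of 16 genes whose symbols begin with Slc7, 8 were lower and 3 higher on the 430 arrays and 6 higher and 1 lower on the exon arrays, and the family was not called (adjusted p = 0.0822 and 0.143).

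Most measured genes of 2 immune receptor families, Cd300 and Sirp, Pilr and Pir, went the other way. Of the Cd300 family, 5 of 6 measured genes were higher on the 430 arrays (median 2.93, adjusted p = 0.000308; adjusted p = 0.0776 with an estimated correlation) and 5 of 7 lower on the exon arrays (median -2.54, adjusted p = 4.2e-05; adjusted p = 0.0713 with an estimated correlation), with Cd300lb at 5.03 and -3.96. All 5 Sirp, Pilr and Pir genes on the 430 arrays were higher (adjusted p = 5.04e-05; adjusted p = 0.0776 with an estimated correlation), among them Pirb at 5.32 and Sirpb1a at 5.49. Members of 1 family could also move apart: on the 430 arrays Adgre1 and Adgre4 changed by 6.30 and 5.86 while Adgre5, which encodes CD97, changed by -2.86, and Tlr3 changed by 4.39 while Tlr7 changed by -1.48; on the exon arrays these were -5.61, -3.02, 3.15, -4.24 and 1.75. Tlr7 is an exception in its family, which had 8 of 11 higher and 1 lower on the 430 arrays (adjusted p = 0.00783; adjusted p = 0.0811 with an estimated correlation) and 5 of 12 lower and 1 higher on the exon arrays (adjusted p = 0.00458; adjusted p = 0.082 with an estimated correlation).

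The 2 tests below differ in when they were chosen: that of the share of calls came after the count of 57 was seen, that of other probe sets before its result. The 57 genes called in the same direction made up 1.51% of genes called on both designs, a share that false calls at the threshold used could give. In 10 of the 37 with several 430 probe sets (27%), another called probe set had the other sign, against 87 of 2324 (3.74%) among genes called in opposite directions (Fisher's exact test, two-sided, p = 1.19e-06), so features that measure different transcripts, or the wrong one, may account for part of them. Both explanations stay open, and no biological one was tested.

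With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. Of the 10, 1, the real one, gave the 20625 probe sets called on the 430 arrays and 1 the 5779 transcript clusters on the exon arrays, and the highest of the other splits gave 0 on each. Each other split mixes arrays of both labels within a group, so the difference between labels enters its spread. With differences this large few calls could be made there, so the 0 is no support for the real split. For gene lists called on the 430 arrays the real split gave 12 and the others 7 to 10, and on the exon arrays 15 and 4 to 9. On each design 1 split, the real one, gave as many. The mixed groups keep part of the difference between labels. So these counts do not show how many lists would be called without any difference.

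On the 430 arrays the control probe sets for 18S ribosomal RNA were lower in the arrays labelled 24 h, by -0.63, -0.89 and -1.38 log2 units for the 3', middle and 5' parts. The difference between 3' and 5' probe sets changed by -0.06 for beta-actin, -0.06 for Gapdh, 0.18 for the transferrin receptor, 0.75 for 18S ribosomal RNA and -0.34 for pyruvate carboxylase, with no common direction. Of the 23238 exon transcript clusters, 6577 carry numbers below those of the named ones and had no symbol here; 617 of them were called higher and 305 lower in the arrays labelled 24 h, at a mean level of 4.93 log2 units against 6.13 for clusters with 1 symbol.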
